A study of Mus musculus with 24 samples.

How the data were processed

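Stomach tissue of 24 mice was profiled on Illumina MouseWG-6 v2 bead arrays, with 8 mice in each of 3 groups. The groups are antrum of gp130WT mice, antrum of gp130FF mice outside tumours (called unaffected antrum) and gp130FF tumour. Per the labels' protocols, total RNA came from frozen tissue and was hybridised as biotin-labelled cRNA. All mice carry the strain label MIXED background (129/sv). The labels give no sex, age, slide or date.

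The deposited values used are probe intensities, and the labels name GenomeStudio as the authors' software. Its version and the settings used are not given in the sources used here. The deposited intensity table holds 45281 probes on each of the 24 arrays, and every probe was matched to the array's annotation by its ID. That the authors subtracted background and brought the arrays to a common distribution, as quantile normalization does, was read from the values, which are on a linear scale. The upper quartile (138.888) and the maximum (49298.1) were shared by all arrays, the widest gap between arrays at any rank of the sorted values was 0.933, and 35.0% of values lay below 0. A further 48 per-sample columns (signals and detection p-values under array barcodes) could not be assigned to samples and were not used. The planned background correction from detection p-values was therefore replaced by the one described next, and the planned filter on detection p-values by a filter on signal.

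Intensities were corrected with normexp (limma 3.58.1 in R 4.3.3, offset 16), which turns values below 0 into small positive ones, and were then put on a log2 scale. No further normalization was applied. A noise estimate of 11.4 was taken from the values below 0. A probe was called above threshold on an array where its deposited intensity exceeded 2 times that estimate (22.7), which 43.2% to 43.3% of probes did per array. Probes above threshold on at least 8 arrays entered the tests, 21039 in all. All arrays share 1 distribution, so a difference in total RNA per cell cannot be seen in these values. The number of arrays limits the precision; the median standard error of a log2 difference was 0.11.

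Probes were named by the gene symbol of the deposited annotation. Symbols were updated with a table of mouse genes on assembly GRCm38.p6, used only for names and for which genes are neighbours. Of the probes, 27740 had a current symbol, 8078 were renamed through a synonym that points to 1 gene, and 9463 kept the symbol as deposited. A gene was represented by its probe with the highest mean over the 24 arrays, which gave 14575 genes. In 4532 genes with 2 or more probes past the filter, 2 probes of the same gene correlated over the arrays with a median of 0.588, against 0.00156 for random pairs.

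Group differences were tested with limma (lmFit and eBayes) on all 24 arrays, with 3 group means and 1 shared estimate of the spread. P-values were two-sided and adjusted by Benjamini-Hochberg over the 14575 genes, and a gene passed at an adjusted p under 0.05. All gene values in the text are log2 differences ± SE with n = 8 arrays per group. A gene above threshold on none of the 8 arrays of the dimmer group has only a bound and is given as at least N-fold, from the brighter group's mean against the threshold level. Folds of genes above threshold on few arrays of the dimmer group are understated, because of the offset, and so are folds of genes that reach the end of the shared scale. Where a gene's probes past the filter did not all pass in the same direction, the number that did is given.

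Gene lists of pathways and cell type markers, 41 with at least 5 members past the filter, were each scored per array as the mean log2 intensity of the members. The 2 groups of each comparison were compared by a two-sided exact permutation test over all 12870 splits of 16 arrays. P-values were adjusted by Benjamini-Hochberg over the 41 lists. The smallest possible p is 1.55e-04. This test keeps the correlation of genes within a list, because the array is the unit, but does not ask whether a list moved more than other genes do. Camera from limma, with an estimated correlation between genes, asks that question and was run on every list. Each list is reported with how many members passed the gene test, adjusted over all genes, and, where the number differs, adjusted over the list alone. A list of sex-linked genes had 4 members past the filter and was not tested; its Y-linked genes were expressed on all 24 arrays.

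Groups, comparisons, lists, the tests and the first set of alternatives were fixed before the data were examined. So was the rule for the genes the text names. It takes the 10 largest rises and 10 largest falls of each of the first 2 comparisons (5 and 5 for tumour versus gp130WT), among genes that passed with all 8 values of one group above all 8 of the other and that do not bear a clone or predicted-gene name. It adds up to 4 of the largest changes in each list, and Il6st, Stat3, Socs3, Il6, Il11, Mtor, Rps6 and Mki67 in any case. The text names part of these genes, and its counts cover all members of a list.

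The test for shared direction of the genotype and tumour differences split the 8 unaffected arrays into 2 sets of 4, 1 set for each comparison, in all 70 ways, so that no array served in both. A simulation of 100 data sets in which tumours were drawn like unaffected antrum, with a single split in each, gave the value without a tumour effect.

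The gene and list tests were tested on simulated data, with the arrays of each comparison and 14575 genes, of which 14375 were unchanged. The means and SDs of the genes were taken from the real data. A far larger share of genes passed in the real comparisons, so the recovery there can differ. At log2 changes of 0.5, 1 and 2 the gene test recovered 67.2%, 98.5% and 100% in the layout of tumour versus unaffected antrum. It recovered 59.7%, 95.5% and 100% for unaffected antrum versus gp130WT, and 62.7%, 97.0% and 98.5% for tumour versus gp130WT. False calls made up 4.32%, 5.03% and 3.91% of the calls in the same order. The list test called 20 of 20 lists of 20 genes shifted by 0.3 in each layout, and 0, 1 and 0 unshifted lists. The simulated genes were drawn independently of each other. How well the test recovers lists whose members correlate, as in the real data, was therefore not tested.

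Alternatives covered the background correction, the filter on dim probes, the groups in the fit, the variance model, array weights, the replicate number as a block, leaving out each array, counting probes, a fold threshold and camera. Without background correction means without normexp: deposited values under 1 were set to 1, and the log2 values were quantile normalized. Dim probes can reach far lower values there than with normexp and its offset. Under another filter a list was scored over the members that then entered, so its set of genes could differ. Alternatives added later were an offset of 50, a floor at the threshold in place of normexp, centring of each array, a stricter filter, leaving out gp130WT replicate 6 with unaffected replicate 6, and random lists as a reference. Slide effects could not be tested, because the array barcodes could not be assigned to samples.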

Results

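Gene expression was measured on 24 bead arrays, 1 per mouse, in antrum of gp130WT mice, in unaffected antrum of gp130FF mice and in gp130FF tumours, with 8 arrays in each group. The gp130FF allele is a knock-in mutation of Il6st, the gene of the gp130 receptor chain that IL-6 family cytokines share; it removes the site through which SOCS3 restrains the receptor, so that STAT3 is over-activated and tumours form in the antrum. The title of the series names interference with mTORC1 as the study's subject. Arrays of the same group correlated at 0.974 to 0.992 in gp130WT antrum, 0.963 to 0.991 in unaffected antrum and 0.971 to 0.989 in tumours. The first principal component, with 69.9% of the variance, placed the tumours at 68.7 to 79.6, the unaffected arrays at -37.8 to -4.63 and the gp130WT arrays at -59.4 to -35.6. Unaffected replicate 6 lay nearest to the tumours.

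Il6st itself was above threshold on all 24 arrays, at log2 intensities of 8.83 to 9.61 in gp130WT antrum, 9.03 to 9.72 in unaffected antrum and 7.99 to 8.62 in tumours. Its transcript level does not show which allele a mouse carries. Il6, a ligand of the receptor, was not above threshold on enough arrays to be tested.

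The comparison of tumour with unaffected antrum asks what sets the tumours apart within gp130FF mice. Among the named genes the antibacterial lectin Reg3b rose by 7.25 ± 0.42 on the log2 scale (152-fold; SE, n = 8 arrays per group here and for every gene value), lactoferrin (Ltf) by 6.83 ± 0.47 (113-fold) and Reg3g by 6.30 ± 0.48 (79.0-fold). In tumours Reg3b and Reg1 reached 15.59, where the scale shared by the arrays ends, so their folds are understated and the order of the largest rises is not exact. The catalytic subunit of the gastric proton pump, Atp4a, was lower by 885-fold as measured (log2 difference -9.79 ± 0.16) and its partner Atp4b by 654-fold (-9.35 ± 0.16). Both folds are limited at both ends: the pump genes were above threshold on 1 and 2 of the 8 tumour arrays, and outside tumours they reached 15.55 and 15.27, close to the end of that scale, so the order of the largest falls is not exact. Of the 14575 genes tested, 9006 (61.8%) passed, 5036 of them higher and 3970 lower in tumours, and 1969 changed at least 2-fold (719 higher, 1250 lower). In 3609 genes (24.8%) the values of the groups did not overlap, where chance gives 0.0155%.

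The other leading rises were the pore-forming claudin Cldn2 (6.17 ± 0.49, 71.9-fold), the cornified envelope protein involucrin, Ivl (5.73 ± 0.32, 53.1-fold), the lectin Reg1 (5.35 ± 0.35, 40.7-fold), the chloride channel Cftr (5.08 ± 0.30, 33.9-fold), the protease-inhibitor domain protein Wfdc18 (5.05 ± 0.37, 33.1-fold), the transcription factor Onecut2 (4.96 ± 0.27, 31.1-fold) and the leucine-rich glycoprotein Lrg1 (4.82 ± 0.30, 28.3-fold). In unaffected antrum Ltf and Cldn2 were above threshold on 5 arrays, Ivl on 4, Reg3b, Reg3g and Onecut2 on 7, and Cftr and Wfdc18 on 2. Among the largest falls, the chitinase Chia1 stood at -9.04 ± 0.21 (525-fold lower), the apolipoprotein Apoa1 at -7.99 ± 0.47 (254-fold), the phospholipase Pla2g1b at -7.97 ± 0.22 (250-fold) and the protein disulfide isomerase Pdia2 at -7.47 ± 0.14 (177-fold). Chia1 was above threshold on 5 tumour arrays and Apoa1 on 4, and outside tumours Chia1 reached 15.59, Pla2g1b 15.47 and Apoa1 15.37 on the scale that ends at 15.59. Hamp2, a hepcidin, fell at least 182-fold, the fatty acid binding protein Fabp3 at least 140-fold, the lipase-related Pnliprp1 at least 87.0-fold and the nuclear receptor Esrrg at least 60.9-fold, since none of the 4 was above threshold in any tumour. The adjusted p of these 20 genes was at most 7.47e-11.

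Of the 41 gene lists, 32 differed between tumour and unaffected antrum, 9 higher and 23 lower (two-sided exact permutation test of list scores). For 21 of them the adjusted p was 3.03e-04, the smallest possible, and it applies below wherever no other adjusted p is given. A list's shift is the difference of its mean score between groups, whose SD within a group was 0.05 to 0.81. With an estimated correlation between genes, only the parietal cell list passed. Counts of members that passed were alike when adjusted over the list alone, except where both are given. The size of many shifts depends on the processing, though the lists named here still passed. Without background correction, with deposited values under 1 set to 1, 16 of the 32 shifts moved by over 1.5 times. The EGF family shrank to 0.28, and the others grew: Wnt targets to -0.94, neurons, glia and Cajal cells to -2.98, cytokines to -1.24, and by less the ATF4, TGF-beta and BMP, matrix, angiogenic, enteroendocrine, tuft, squamous, pancreatic acinar, fibroblast, endothelial, macrophage and erythrocyte lists. With no filter, genes too dim for the tests joined the lists, so a score could cover a different set of genes. There 8 shifts shrank, neutrophils to 0.31 and by less the acute phase, cytokine, enteroendocrine, squamous, pancreatic acinar, adipocyte and mast cell lists.

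The STAT3-induced list shifted by 1.11: 20 of 29 rose and 2 fell, and the median member stood at 0.60 (adjusted p = 0.305 with an estimated correlation). They included Timp1, an inhibitor of metalloproteinases, at 2.27 ± 0.30, and the feedback inhibitor Socs3 at 1.92 ± 0.30, while Stat3 rose by 0.45 ± 0.10 (adjusted p 3.19e-04). The acute phase and antimicrobial list shifted by 1.98 with 9 of 19 members higher and 3 lower and the median member at 0.72 (adjusted p = 0.305 with an estimated correlation); it shares Reg3b, Reg3g, Lrg1 and Saa3 with the STAT3 list. Of the 22 neutrophil genes listed, only 5 were past the filter. Their list shifted by 1.72 (0.31 with no filter), with 4 of the 5 higher and the median member at 0.36 (adjusted p = 0.178 with an estimated correlation). Most of that shift is Ltf, which epithelia also secrete and which the acute phase list holds too; the gelatinase Mmp9 rose by 0.91 ± 0.26 and was above threshold on 5 unaffected arrays. Of the EGF family, 8 of 11 members rose and 1 fell, a shift of 0.58 (adjusted p = 0.327 with an estimated correlation). The ligand Areg stood at 2.12 ± 0.27 and the receptor Erbb2 at 1.15 ± 0.10.

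Cell division genes rose as well. The proliferation list shifted by 0.74 (adjusted p 8.69e-04, and adjusted p = 0.488 with an estimated correlation), and 23 of 32 members rose with none lower (24 adjusted over the list alone). The cytokinesis factor Prc1 rose by 2.67 ± 0.27, the mitotic activator Cdc20 by 1.95 ± 0.25 (3 of 4 probes) and the proliferation antigen Mki67 by 1.54 ± 0.30 (1 of 2 probes). Immediate-early genes shifted by 0.38 (adjusted p 0.0204; adjusted p = 0.634 with an estimated correlation), 12 of 18 higher and 3 lower. Ier3 stood at 1.39 ± 0.19 and Klf2 at -0.99 ± 0.17. Without background correction the immediate-early list did not pass (adjusted p 0.0774). The squamous epithelium list shifted by 1.45 with 6 of 9 members higher (adjusted p = 0.415 with an estimated correlation), among them Ivl and Sprr1a, at 1.74 ± 0.31, another envelope protein. Fat and sterol synthesis genes rose in 17 of 24 cases and fell in 1 (18 and 1 adjusted over the list alone), a shift of 0.45 (adjusted p 0.00106; adjusted p = 0.415 with an estimated correlation). The desaturase Scd2 stood at 1.38 ± 0.10 and the elongase Elovl6 at 1.28 ± 0.17. Of the 7 pentose phosphate pathway genes, 5 rose, a shift of 0.37 (adjusted p 0.00172; adjusted p = 0.377 with an estimated correlation). Tkt stood at 0.96 ± 0.12 (1 of 2 probes) and Taldo1 at 0.53 ± 0.07.

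Lists of the specialised gland cells of the stomach fell in tumours. Outside tumours some of their genes lay at or near the end of the scale, such as Atp4a (up to 15.55), Chia1 and Cblif (both up to 15.59). How much acid-secreting tissue each sample held is not recorded. A difference in the tissue sampled and a loss in tumours therefore cannot be told apart. The parietal cell score was 7.65 ± 0.10 (SD, n = 8) in tumours and 11.54 ± 0.27 in unaffected antrum, a shift of -3.89, with 11 of 13 members lower and 1 higher (adjusted p = 0.0313 with an estimated correlation). The chief cell list fell by 3.50, with 5 of 7 members lower (1 higher and 5 lower adjusted over the list alone; adjusted p = 0.0676 with an estimated correlation), among them gastric intrinsic factor, Cblif, at -6.05 ± 0.18 (with 15.59 reached outside tumours) and the pepsinogen Pga5 at -5.28 ± 0.24. Of the enteroendocrine list, 12 of 16 members fell and 2 rose, a shift of -2.05 (adjusted p = 0.147 with an estimated correlation), with the hormones ghrelin (Ghrl) at -5.98 ± 0.29 (with 15.59 reached outside tumours) and somatostatin (Sst) at -5.43 ± 0.30. The pancreatic acinar list shifted by -2.12 (adjusted p = 0.147 with an estimated correlation), with 7 of 12 members lower and 3 higher (7 and 4 adjusted over the list alone). The colipase Clps stood at -3.72 ± 0.09 (with 15.39 reached outside tumours).

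Mucous and tuft cell markers moved in both directions. The gland mucous list shifted by -0.31 (adjusted p 0.0257; adjusted p = 0.488 with an estimated correlation), with 6 of 11 members lower and 2 higher: the glycosyltransferase A4gnt stood at -1.78 ± 0.18, the water channel Aqp5 at 2.59 ± 0.32 and the transferase Galnt6 at 2.00 ± 0.15. The surface mucous list, at -0.17, did not pass (adjusted p 0.286; the median of its members was 0.10), with 2 of 10 members higher, 2 lower and 6 not passing. The surface mucin Muc5ac fell by 2.44 ± 0.47 (with 15.33 reached in unaffected antrum), with an SD of 1.77 among tumours, and Gkn3 rose by 0.82 ± 0.19. The tuft cell list shifted by -0.29 (adjusted p 0.0434; adjusted p = 0.581 with an estimated correlation), with 8 of 12 members lower and 2 higher. Cd24a stood at -0.78 ± 0.15 and the actin-binding Avil at 1.05 ± 0.15. Intestinal epithelium markers, at 0.19, did not pass as a list (adjusted p 0.405); 9 of 20 rose and 3 fell. The alkaline phosphatase Alpi stood at 3.95 ± 0.42 (above threshold on 4 unaffected arrays) and Apoa1 at the other extreme. The gland mucous call was lost without unaffected replicate 3 (adjusted p 0.0547) or tumour replicate 8 (0.0508). The tuft call was lost without any of unaffected replicates 3 to 8 or of tumour replicates 1, 3, 4, 6, 7 and 8 (0.0504 to 0.0834), and with no filter (0.0519) or an offset of 50 (0.0631).

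The muscle wall and connective tissue were lower too. All 19 smooth muscle members fell, a shift of -2.67 (adjusted p = 0.178 with an estimated correlation). Among intermediate filament proteins, Synm stood at -4.22 ± 0.40 and desmin (Des) at -4.03 ± 0.47. Of the fibroblast list, 18 of 20 fell (19 adjusted over the list alone), a shift of -1.64 (adjusted p = 0.128 with an estimated correlation). The matrix protein Dpt stood at -3.15 ± 0.17 and the collagen Col6a1 at -2.81 ± 0.14. Enteric neuron, glia and Cajal cell markers fell in 12 of 15 cases and rose in 2, a shift of -1.11 (adjusted p = 0.147 with an estimated correlation). The neuropeptide Vip stood at -4.20 ± 0.60 (above threshold on 5 tumour arrays) and the receptor Kit at -2.34 ± 0.18. Endothelial markers fell in 14 of 16 cases, a shift of -1.07 (adjusted p 0.00106; adjusted p = 0.377 with an estimated correlation). Plvap stood at -2.84 ± 0.25 and Ramp2 at -1.58 ± 0.16. Of the erythrocyte list, 5 of 6 fell, a shift of -1.27 (adjusted p = 0.305 with an estimated correlation). Among globins, Hba-a1 stood at -2.43 ± 0.28 and Hbb-b1 at -2.12 ± 0.28 (10 of 11 probes). The adipocyte list shifted by -0.72 although 3 of its 7 members rose and 3 fell, and the median member stood at -0.05 (adjusted p = 0.714 with an estimated correlation); the lipoprotein lipase Lpl fell by 5.93 ± 0.13 and the lipid droplet protein Cidea rose by 2.05 ± 0.17.

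Immune markers were mostly lower. Antigen presentation through MHC class II shifted by -1.71, with 5 of 7 members lower (adjusted p = 0.488 with an estimated correlation). The invariant chain Cd74 stood at -2.86 ± 0.42 and H2-Aa at -2.39 ± 0.38. The macrophage and dendritic cell score was 6.51 ± 0.15 (SD, n = 8) in tumours and 7.51 ± 0.29 in unaffected antrum, and 13 of 19 members fell and 1 rose (adjusted p = 0.327 with an estimated correlation). The lysozyme Lyz2 stood at -2.33 ± 0.22, the macrophage receptor Adgre1 at -2.04 ± 0.17 (above threshold on 6 tumour arrays) and the endotoxin co-receptor Cd14 at 2.03 ± 0.24. Interferon response genes shifted by -0.68 (adjusted p 0.00410; adjusted p = 0.579 with an estimated correlation), 14 of 25 lower and 2 higher (15 and 2 adjusted over the list alone). Among antiviral genes, Rsad2 stood at -1.97 ± 0.31 and Ifit3 at -1.61 ± 0.18. Cytokines and chemokines shifted by -0.56, 8 of 16 lower and 2 higher (adjusted p = 0.415 with an estimated correlation). Cxcl12 stood at -2.39 ± 0.20 and the eotaxin Ccl11 at -2.20 ± 0.24. Mast cell markers shifted by -1.14, 4 of 6 lower with a median member at -0.68 (adjusted p = 0.324 with an estimated correlation). The histamine-forming enzyme Hdc, which the enteroendocrine list holds too, stood at -3.81 ± 0.24, and Kit, which the neuron and Cajal cell list holds too, at -2.34 ± 0.18. T and NK cell markers did not pass (shift 0.01, adjusted p 0.824; 2 of 9 members rose and 2 fell, 2 and 1 adjusted over the list alone), but without background correction they shifted by -0.50 (adjusted p 0.00341). B and plasma cell markers did not pass (shift -0.14, adjusted p 0.0800, median member 0.10; 1 of 5 rose and 2 fell), but passed without tumour replicate 3 (-0.18, adjusted p 0.0154), with no filter (0.0141) and without background correction (-0.94, 3.19e-04).

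Among the receptor and mTOR genes, Il6st fell by 0.90 ± 0.11 (adjusted p 1.88e-07) and the IL-11 receptor chain Il11ra1 fell by 1.51 ± 0.11. The oncostatin M receptor Osmr rose by 1.61 ± 0.20. The ligand Il11 rose by 0.72 ± 0.22 (adjusted p 0.00592), and by 0.48 without tumour replicate 5 (adjusted p 0.00284), and was above threshold on 7 tumour and 2 unaffected arrays. The IL-6 family list did not pass (shift -0.11, adjusted p 0.0800, median member 0.09; 2 of 9 rose and 4 fell), but passed without tumour replicate 5 (-0.15, adjusted p 0.00987), with an offset of 50 (0.0331) and with a stricter filter (-0.33, 2.89e-04). The kinase Mtor stood at -1.47 ± 0.14 (adjusted p 8.90e-10), its activator Rheb at -0.85 ± 0.10 and the ribosomal protein Rps6 at -0.48 ± 0.11 (adjusted p 4.29e-04). The mTORC1 inhibitor Ddit4 rose by 1.72 ± 0.20. The mTOR list did not pass (shift -0.02, adjusted p 0.363), with 10 of 28 members higher and 11 lower. These are transcript levels of whole tissue, and pathway activity was not measured. Cell type lists differed between the same groups. For these genes, and for the lists that rose, a change within cells cannot be told apart from a change of cell types.

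Pathway lists that fell did so on arrays on which cell type markers were lower too, parietal cells by -3.89, smooth muscle by -2.67 and fibroblasts by -1.64. Oxidative phosphorylation genes fell in 26 of 30 cases with none higher, a shift of -0.68 (adjusted p = 0.178 with an estimated correlation). Sdhb stood at -1.33 ± 0.12 and Ndufa4 at -1.31 ± 0.10. ATF4 and amino acid response genes shifted by -0.56 (adjusted p = 0.305 with an estimated correlation), 12 of 20 lower and 1 higher (12 and 2 adjusted over the list alone). The transaminase Gpt2 stood at -1.32 ± 0.16 and the pseudokinase Trib3 at 1.29 ± 0.22. TGF-beta and BMP pathway genes shifted by -0.48 (adjusted p = 0.0676 with an estimated correlation), 12 of 20 lower and 3 higher. The ligand Bmp4 stood at -2.58 ± 0.13 and its target Id2 at -1.15 ± 0.19 (2 of 3 probes). Matrix and proteolysis genes shifted by -0.56 (adjusted p 0.00127; adjusted p = 0.415 with an estimated correlation), 14 of 24 lower and 8 higher. Among metalloproteinase inhibitors, Timp2 stood at -2.62 ± 0.13 and Timp1 at 2.27 ± 0.30. Angiogenic factors shifted by -0.50 (adjusted p 0.00189; adjusted p = 0.415 with an estimated correlation), 4 of 14 lower and 1 higher and a median member at -0.21, with Vegfb, which the parietal list holds too, at -3.18 ± 0.15 and the co-receptor Nrp1 at -2.25 ± 0.17. Wnt targets and antral stem cell genes shifted by -0.17 (adjusted p 0.0231; adjusted p = 0.538 with an estimated correlation), 10 of 20 lower and 8 higher (11 and 8 adjusted over the list alone). The adhesion receptor Cd44 stood at 3.25 ± 0.25 on its brightest probe and at 0.54 to 2.44 on 4 others, all past the threshold. The Wnt list's call was lost without unaffected replicate 7 (adjusted p 0.0543) or 8 (0.0526) and with an offset of 50 (0.390). Glycolysis (-0.02, adjusted p 0.643; 7 of 16 higher, 3 lower, median member 0.11), ribosome biogenesis (0.10, adjusted p 0.363; 10 of 27 higher, 5 lower) and the heat shock and unfolded protein response (-0.18, adjusted p 0.335; 8 of 24 lower, 1 higher, or 7 and 1 adjusted over the list alone) did not pass.

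**Figure D1:**
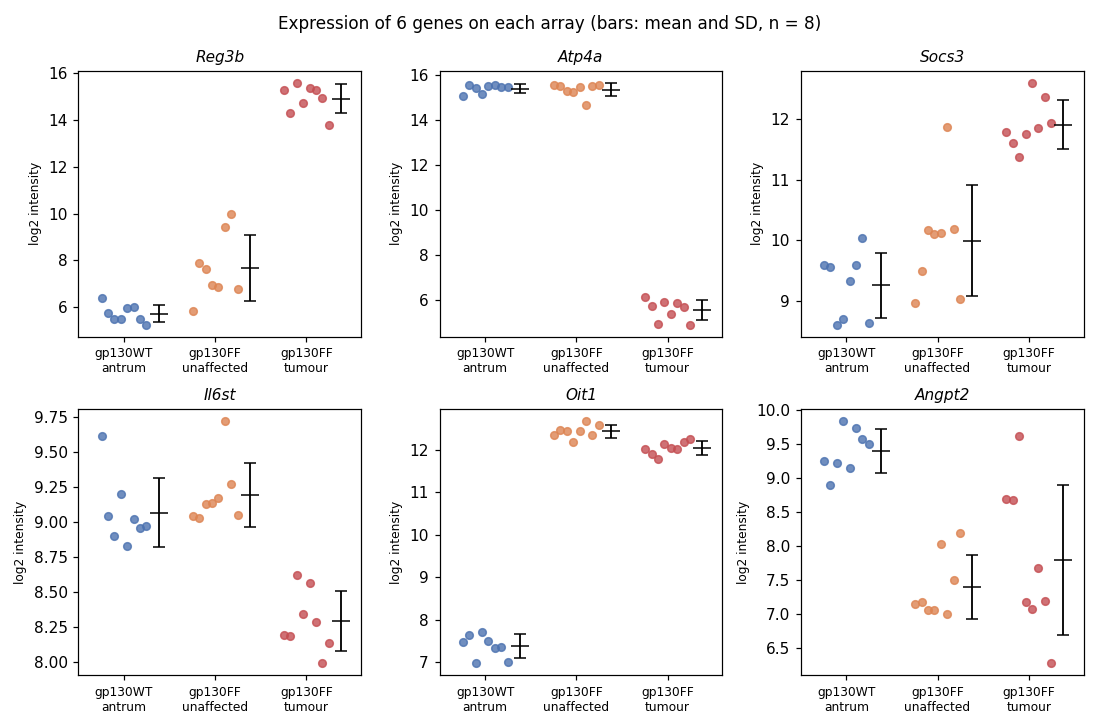
Log2 intensity of Reg3b, Atp4a, Socs3, Il6st, Oit1 and Angpt2 in gp130WT antrum, unaffected gp130FF antrum and gp130FF tumours, with 1 point per array and a bar for the mean and SD of 8 arrays. From unaffected antrum to tumour Reg3b differed by 7.25 and Atp4a by -9.79 on the log2 scale, and Oit1 rose by 5.05 from gp130WT to unaffected antrum.

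The comparison of unaffected gp130FF antrum with gp130WT antrum asks what the genotype changes outside tumours. It was led by single genes that differed between the groups with a wide gap: Oit1, a secreted factor, rose by 5.05 ± 0.10 (33.2-fold), Gramd4 by 4.45 ± 0.18 (21.9-fold) and the vesicle protein Lrba by 3.01 ± 0.09 (8.05-fold). The lipid kinase Pik3c2g had a log2 intensity of 7.99 ± 0.39 (SD, n = 8) in unaffected antrum and 10.99 ± 0.24 in gp130WT antrum (8.00-fold lower, SE of the difference 0.13, 2 of 3 probes). The collagen chain Col1a2 stood at -2.71 ± 0.16 (6.54-fold). Genes that were higher still in tumours rose here too, Reg1 by 2.38 ± 0.35, Reg3g by 2.10 ± 0.48 and Reg3b by 1.94 ± 0.42 (1 of 2 probes). Both Reg3 genes were above threshold on 1 gp130WT array and 7 unaffected arrays. Of the 14575 genes, 1912 (13.1%) passed, 839 higher and 1073 lower in unaffected antrum, and 195 changed at least 2-fold (118 higher, 77 lower). In 317 genes (2.17%) the values of the groups did not overlap, where chance gives 0.0155%. Leaving out 1 array gave 1366 to 2063 genes, the fewest without gp130WT replicate 4.

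Further leading rises were Wdr92 (2.74 ± 0.27, 1 of 2 probes), the neuropeptide galanin, Gal (2.54 ± 0.61), Necap2 (2.39 ± 0.10, 1 of 2 probes), the peroxisomal oxidase Acox2 (2.02 ± 0.14), the alarmin Il33 (2.02 ± 0.29) and the glycosyltransferase B3galt6 (1.79 ± 0.08). H2-Bl was at least 2.23-fold higher, being above threshold on none of the gp130WT arrays. The other leading falls were the vessel ligand Angpt2 (-1.99 ± 0.33), the retinol binding protein Rbp7 (-1.94 ± 0.19), Ocel1 (-1.93 ± 0.10), the lipid droplet protein Pnpla3 (-1.83 ± 0.26), Tm6sf2 (-1.81 ± 0.16), Arrdc3 (-1.54 ± 0.17), the methyl cycle enzyme Ahcy (-1.53 ± 0.10) and the von Willebrand factor, Vwf (-1.52 ± 0.24). Pnpla3 and Tm6sf2 were above threshold on 1 unaffected array each, and Gramd4 on 6 gp130WT arrays. The adjusted p of these 20 genes was at most 0.00718, that of Gal, which did not pass without background correction (adjusted p 0.152). Of the genes with a wide gap, several are neighbours on a chromosome: Acox2 and Oit1 are adjacent among the tested genes, and Tm6sf2, Ocel1, Rbp7 and Necap2 each lie near other such genes.

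Of the 41 lists, 13 differed, 5 higher and 8 lower in unaffected antrum, with 8 to 16 when 1 array was left out (8 without gp130WT replicate 8 and without unaffected replicate 6). Without background correction the shifts of 5 grew by over 1.5 times: mast cells to -1.27, acute phase genes to 1.37, STAT3-induced genes to 0.69, B and plasma cells to -0.28 and Wnt targets to -0.26. With no filter the acute phase shift shrank to 0.49 and the B and plasma cell shift to -0.08. None passed with an estimated correlation, where 0 of 41 did, against 22 at an unadjusted p under 0.05 in the permutation test. The STAT3-induced list shifted by 0.39 (adjusted p 0.0159; adjusted p = 0.417 with an estimated correlation): 8 of 29 members rose and 1 fell (13 and 2 adjusted over the list alone). Timp1 stood at 1.14 ± 0.30. Socs3 stood at 0.74 ± 0.30 (adjusted p 0.107) and Stat3 at 0.27 ± 0.10 (adjusted p 0.0681), neither past the threshold, although 1 of the 3 Stat3 probes, a dimmer one, passed at 0.46 ± 0.11 (adjusted p 0.00660 over all probes). On its brightest probe Stat3 passed without gp130WT replicate 1 (adjusted p 0.0487) or 2 (0.0466) or unaffected replicate 8 (0.0424), and Socs3 without unaffected replicate 1 (0.0470), while without unaffected replicate 6 Socs3 stood at 0.47 (adjusted p 0.235). The acute phase and antimicrobial list shifted by 0.75 (adjusted p 0.0181; adjusted p = 0.417 with an estimated correlation), with 6 of 19 members higher (8 adjusted over the list alone). The oxidase maturation factor Duoxa2 stood at 2.36 ± 0.43. Surface mucous markers shifted by 0.46 (adjusted p 0.00637; adjusted p = 0.417 with an estimated correlation), 4 of 10 higher (5 adjusted over the list alone), with a median member at 0.24. The protease Capn8 stood at 1.22 ± 0.23 and Lypd8, which keeps bacteria off the epithelium, at 1.16 ± 0.21. Gland mucous markers shifted by 0.29 (adjusted p 0.0183; adjusted p = 0.547 with an estimated correlation), 4 of 11 higher and 1 lower. A4gnt stood at 0.73 ± 0.18 and Galnt6 at 0.57 ± 0.15. Tuft cell markers shifted by 0.38 (adjusted p 0.0377; adjusted p = 0.417 with an estimated correlation), 4 of 12 higher (9 adjusted over the list alone). The leukotriene synthase Ltc4s stood at 0.64 ± 0.14. The tuft cell call was lost without any of gp130WT replicates 1, 3, 5, 7 and 8 or unaffected replicates 3, 4, 5, 6 and 8 (0.0515 to 0.0686), without background correction (0.0671) and with a floor at the threshold (0.0544).

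Vessel markers fell. All 16 endothelial members were lower adjusted over the list alone, and 12 when adjusted over all genes, a shift of -0.68 at the smallest possible p (adjusted p 0.00319; adjusted p = 0.417 with an estimated correlation). Ramp2 stood at -0.78 ± 0.16, Esam at -0.77 ± 0.16 and Vwf at -1.52 ± 0.24. Angiogenic factors shifted by -0.44 at the same p (adjusted p 0.00319, and adjusted p = 0.417 with an estimated correlation), 6 of 14 lower (7 lower and 2 higher adjusted over the list alone), among them Angpt2, Nrp1 at -0.63 ± 0.17 and Vegfb at -0.58 ± 0.15. Part of this shift is Angpt2 (-1.99), a gene with a wide gap between the groups. Erythrocyte markers shifted by -0.49 (adjusted p 0.0181; adjusted p = 0.608 with an estimated correlation), 2 of 6 lower, and mast cell markers by -0.60 (adjusted p 0.0183; adjusted p = 0.417 with an estimated correlation), 2 of 6 lower (3 adjusted over the list alone). The mast cell protease Cpa3 stood at -1.18 ± 0.31 and was above threshold on 3 unaffected arrays.

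Smaller list shifts passed for oxidative phosphorylation, Wnt targets, mTOR components and B cells. Oxidative phosphorylation genes shifted by -0.18 (adjusted p 0.0308; adjusted p = 0.547 with an estimated correlation), 9 of 30 lower (17 adjusted over the list alone). Ndufs8 stood at -0.39 ± 0.09. The oxidative phosphorylation call was lost without gp130WT replicate 3 or 8 or unaffected replicate 4 or 6 (0.0550 to 0.0680). Wnt targets and stem cell genes shifted by -0.13 (adjusted p 0.0308; adjusted p = 0.634 with an estimated correlation), 4 of 20 lower, with a median member at -0.04. The transcription factor Sp5 stood at -1.02 ± 0.21 and the receptor Tnfrsf19 at -0.90 ± 0.13. The Wnt list's call was lost without any of gp130WT replicates 1, 7 and 8 or unaffected replicates 2, 4, 5 and 6 (0.0519 to 0.0660), with no filter (0.0557) and with a floor at the threshold (0.0689). The mTOR list shifted by -0.06 (adjusted p 0.0308; adjusted p = 0.634 with an estimated correlation), with 2 of 28 members lower; the call was lost without gp130WT replicate 1, 3, 7 or 8 or unaffected replicate 4 or 6 (0.0515 to 0.0660), without background correction (0.0843) and with a floor at the threshold (0.0896). Mtor (-0.10 ± 0.14, adjusted p 0.697), Rps6 (0.23 ± 0.11, 0.164), Il6st (0.13 ± 0.11, 0.512), Mki67 (0.30 ± 0.30, 0.574) and Il11 (0.04 ± 0.22, 0.932) did not pass. B and plasma cell markers shifted by -0.17 (adjusted p 0.0269; adjusted p = 0.679 with an estimated correlation), with 1 of 5 lower and a median member at -0.06; the call was lost without gp130WT replicate 8 (0.0517) or unaffected replicate 6 (0.0566), and with no filter (0.361).

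Interferon response and MHC class II lists depended on a single array. The interferon list, at 0.52, did not pass with all arrays (adjusted p 0.0924; 6 of 25 members higher, 1 lower, and 8 and 1 adjusted over the list alone). Among antiviral genes, Oas2 stood at 2.17 ± 0.50, Irf7 at 1.21 ± 0.27 and Oasl1 at 1.04 ± 0.20. Without gp130WT replicate 6 the interferon list shifted by 0.75 (adjusted p 0.00319), and the MHC class II list by 0.54 (adjusted p 0.0467), against 0.09 (adjusted p 0.928; 0 of 7 members passed) with all arrays. That array scored 12.1 for MHC class II, where the other 7 gp130WT arrays lay between 8.16 and 8.61. Intestinal epithelium markers, at 0.55, did not pass (adjusted p 0.0589; 5 of 20 higher, 2 lower) although the goblet cell genes Clca1 and Fcgbp rose by 2.66 ± 0.63 and 2.18 ± 0.61 (Fcgbp above threshold on 2 gp130WT arrays); the list passed without unaffected replicate 1 (adjusted p 0.0299) or 2 (0.0382). Macrophage markers did not pass (-0.40, adjusted p 0.0705; 5 of 19 lower, 10 adjusted over the list alone), but that list passed without unaffected replicate 3 (adjusted p 0.0127) and stood at -0.24 without gp130WT replicate 6 (adjusted p 0.106). Its member Adgre1 stood at -0.77 ± 0.17 (1 of 2 probes). Parietal (-0.19, adjusted p 0.126), chief (-0.20, 0.147) and smooth muscle markers (0.20, 0.316) did not pass; without unaffected replicate 6 the parietal list stood at -0.10 and the smooth muscle list at 0.13.

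**Figure D2:**
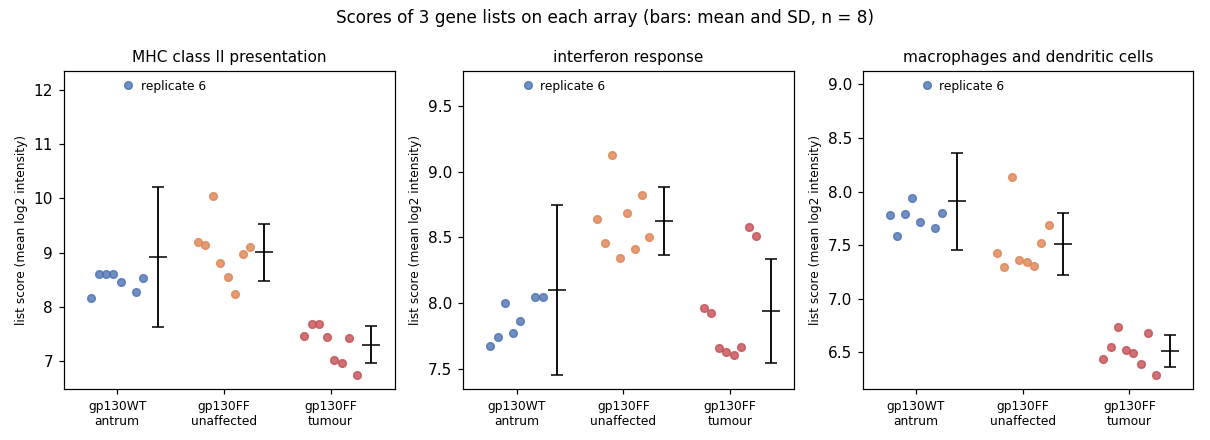
Scores (mean log2 intensity of the members) of the MHC class II, interferon response and macrophage and dendritic cell lists in the 3 groups, with 1 point per array and a bar for the mean and SD of 8 arrays. gp130WT replicate 6 scored 12.1 for MHC class II against 8.16 to 8.61 on the other gp130WT arrays.

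The comparison of tumour with gp130WT antrum joins both differences. As measured, Reg3b was 583-fold higher in tumours (9.19 ± 0.42), Reg3g 339-fold (8.41 ± 0.48), Reg1 211-fold (7.72 ± 0.35), Ltf 163-fold (7.35 ± 0.47) and Cldn2 133-fold (7.05 ± 0.49); Reg3b, Reg3g and Cldn2 were above threshold on 1 gp130WT array and Ltf on 3, and Reg3b and Reg1 reached the end of the scale in tumours. Atp4a was 915-fold lower (-9.84 ± 0.16), Atp4b 651-fold (-9.35 ± 0.16) and Chia1 542-fold (-9.08 ± 0.21), with the limits named above for tumour versus unaffected antrum; lower too were Hamp2 at least 318-fold and Fabp3 at least 215-fold. Of the 14575 genes, 9773 (67.1%) passed, 5265 higher and 4508 lower, and 2750 changed at least 2-fold. In 5038 genes (34.6%) the values of the groups did not overlap, where chance gives 0.0155%.

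Of the lists, 34 of 41 differed (11 higher, 23 lower), 25 of them at the smallest possible p (adjusted p 2.55e-04), and 0 passed with an estimated correlation (34 in the permutation test at an unadjusted p under 0.05). Without background correction 16 of the 34 shifts moved by over 1.5 times, the intestinal (to 1.22) and endothelial (to -2.72) lists named below among them, and most of all B and plasma cells (to -1.23), Wnt targets (to -1.20) and neurons, glia and Cajal cells (to -2.77). With no filter 10 shrank, most of all neutrophils (to 0.29). The STAT3-induced score was 9.97 ± 0.19 (SD, n = 8) in tumours and 8.47 ± 0.16 in gp130WT antrum, with 21 of 29 members higher and 3 lower and a median member at 0.79 (adjusted p = 0.234 with an estimated correlation). Socs3 stood at 2.66 ± 0.30, Stat3 at 0.72 ± 0.10 and Timp1 at 3.42 ± 0.30. Intestinal epithelium markers shifted by 0.73, 14 of 20 higher and 4 lower (15 and 4 adjusted over the list alone; adjusted p = 0.509 with an estimated correlation). Fcgbp stood at 5.53 ± 0.61 (above threshold on 2 gp130WT arrays), Alpi at 4.97 ± 0.42 (on 1) and Clca1 at 4.54 ± 0.63 (with 15.47 reached in tumours). All 16 endothelial markers (shift -1.75) and all 19 smooth muscle markers (-2.46) fell (adjusted p = 0.243 with an estimated correlation for both). Plvap stood at -3.51 ± 0.25. Il6st stood at -0.78 ± 0.11 and Mtor at -1.57 ± 0.14, with the limit on cell types named above. Mki67 rose by 1.84 ± 0.30 (1 of 2 probes) and Il11 by 0.76 ± 0.22 (adjusted p 0.00341). Rps6 fell by 0.25 ± 0.11 (adjusted p 0.0441), a call lost without any of gp130WT replicates 3, 5, 6 and 8 or tumour replicates 2, 4, 5, 6, 7 and 8 (0.0523 to 0.113).

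**Figure D3:**
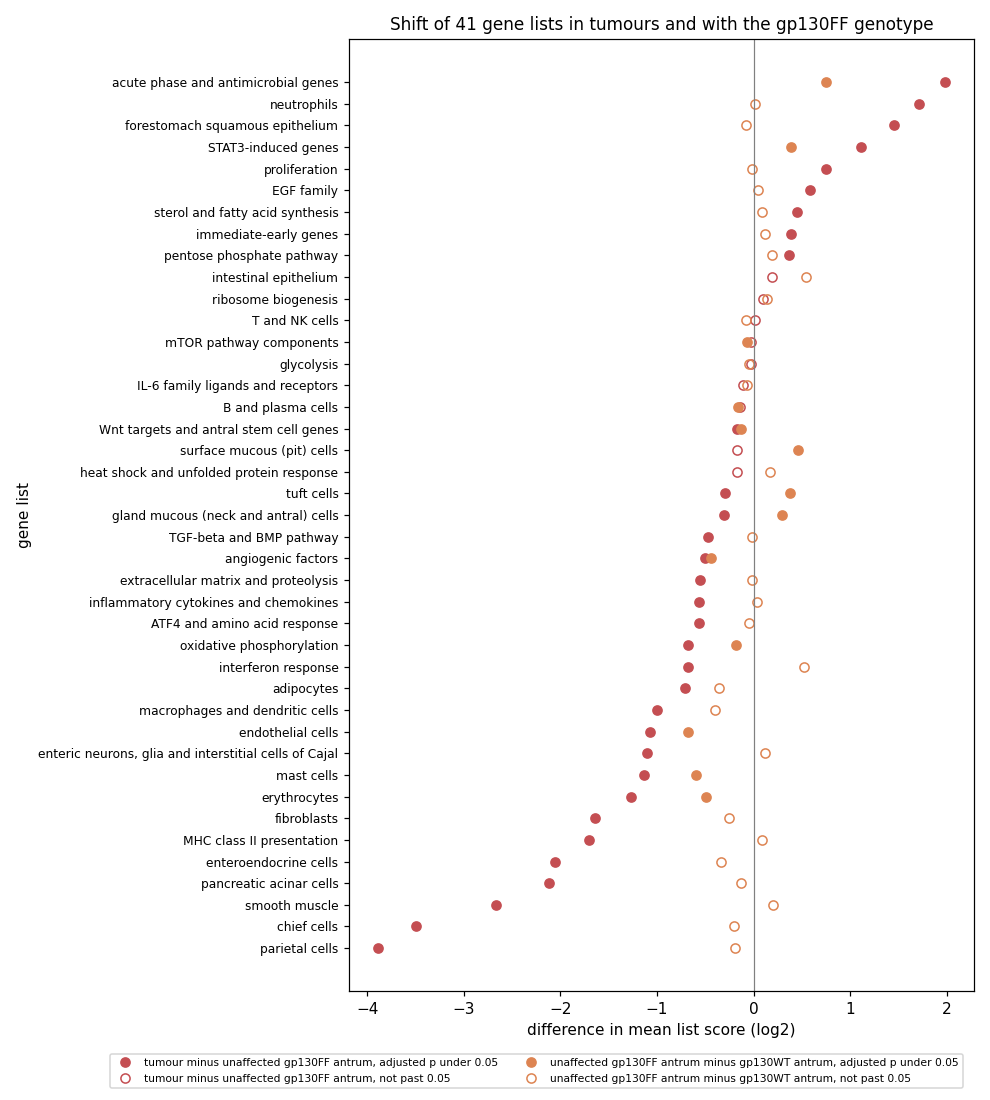
Shift of each of the 41 gene lists (difference of mean log2 scores) for tumour versus unaffected antrum and for unaffected versus gp130WT antrum; filled points passed at an adjusted p under 0.05 and open points did not. Parietal cell markers shifted by -3.89 between tumour and unaffected antrum and by -0.19 between the genotypes (-0.10 without unaffected replicate 6).

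Whether genes that differed with the genotype moved further the same way in tumours was counted gene by gene. With the unaffected arrays split so that none served in both comparisons, a median of 76.4% of the genes called between genotypes moved the same way from unaffected antrum to tumour (62.1% to 86.9% over 70 splits, with a median of 838.5 genes called). It was 72.2% for genes that rose and 78.8% for genes that fell, where 56.9% of all genes were higher in tumours. With tumours simulated like unaffected antrum the value was 50.7% (20.8% to 76.5% over 100 simulations). Each simulation used a single split, so this range is wider than that of a median over 70 splits would be. It cannot decide the question. With all 8 unaffected arrays in both comparisons the observed share was 75.9%, above the simulated range (34.8%, 15.4% to 58.7%). These simulated tumours had no changes of their own, so the share that unrelated tumour changes would give was not simulated. Among genes called in both comparisons, 479 rose in both, where independent lists would share 289.9, and 657 fell in both (292.3). A further 112 rose with the genotype and fell in tumours (228.5), and 112 did the reverse (370.7). The covariance of the log2 differences across genes was 0.0816, against -0.00988 simulated with no group difference, which leaves 0.0915; the correlation was 0.298 (0.316 with split arrays), and genes are not independent replicates.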

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

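The tests of single genes with a wide gap, the test of the label of gp130WT replicate 6, the tests of lower muscle, stroma and acid gland markers and the counts over other groupings of the arrays were chosen only after the results were seen; the B and T cell test and the macrophage test of gp130WT replicate 6 were written before their results. Values that stood apart in their group of 8 arrays were searched for by the gap to the nearest other array as a share of the group's range. Of 492 groups of 8 values, 52 held such a value (13 list scores and 39 genes), where chance gives about 1 in 20 groups, or 24.6. By array, 13 belong to gp130WT replicate 6, 11 to unaffected replicate 6 and 9 to gp130WT replicate 1. For the numbers of genes that changed, groupings drawn at random gave fewer genes in all 3 comparisons: of 100 groupings of the 16 arrays, 1, the real one, called as many genes. Such groupings cannot tell a difference between the groups from a slide effect. Tumour versus unaffected antrum gave 9006 genes and the highest other grouping 6468, unaffected versus gp130WT antrum 1912 and 1252, and tumour versus gp130WT antrum 9773 and 7841. The highest other grouping left 7 of 8 arrays on their real side each time.

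Between unaffected and gp130WT antrum, 32 genes differed by a log2 difference of at least 1 with a gap of at least 0.5 between the groups (22 higher and 10 lower, and 12 more with clone or predicted names), among them Oit1, Gramd4, Lrba and Pik3c2g. A sequence variant that affects only 1 probe is excluded as the cause of every such difference. In 7 of 14 genes with a further probe that probe was called the same way with at least 0.5 of the change, in 2 (B3galt6 and Zfp869) with less, and in 5 it was not. A graded gp130FF response that goes further in tumours cannot be told apart from other causes. With such genes chosen on 4 unaffected arrays and counted on the other 4, a median of 31.7% were called further the same way (16.3% to 57.8% over 70 splits). A median of 23.3% were called the opposite way (10.8% to 34.9%). The share that went further stayed below the level set for such a response in every split. It lay above the level set against it in some, so the test cannot decide. A segment carried along with Il6st is excluded as the cause of most, since 9.68% (3 of 31: Arsb, Mrps27 and Paip1) lie within 100 tested genes on either side of it, although that is more than their share of tested genes (Fisher exact p 0.00348). A candidate explanation for part of the set is chromosome segments of another strain fixed in 1 of the mouse lines: 10 pairs of these genes lie within 25 tested genes of each other, against a median of 2 and an upper limit of 5 in 10000 random sets, with runs of Zfp869, Tm6sf2 and Rfxank and of Ocel1, B3gnt3 and Cyp4f18 on chromosome 8, of Agtrap, Rbp7 and Klhl21 and of Necap2 and Hspb7 on chromosome 4, and of Acox2 and Oit1 on chromosome 14. It stays a hypothesis found and tested on the same arrays, and no genotype was used here. For genes outside such runs an effect of the gp130FF allele stays open. A variant that affects only 1 probe stays open there too, but not for Twistnb, Pik3c2g, Angpt2, Ahcy, Dusp13 and Raet1b. In these a further probe was called the same way with at least 0.5 of the change. Whether the probes of a gene overlap was not checked, so variants under more than 1 probe stay open for these genes too.

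gp130WT replicate 6 stood apart with a score of 12.09 for MHC class II (the other 7 gp130WT arrays 8.16 to 8.61, their mean 3.63 lower) and 9.66 for the interferon response (7.67 to 8.05), and Cd74 was 15.5-fold, H2-Ab1 12.5-fold, H2-Aa 11.4-fold and H2-Eb1 11.1-fold above the mean of the other 7. A gp130FF sample under the gp130WT label is excluded, since in 97.0% of the genes with a wide gap (32 of 33, chosen without this array) it lay nearer to the other gp130WT arrays. More macrophages and dendritic cells may account for part of the pattern: their score was higher by 1.24 than the mean of the other 7 (SD 0.113), with Lyz2 at 11.54, and the list shares no member with the MHC class II list. B and T cells cannot be told apart from other sources, since the T and NK cell score was higher by 0.79 while the B and plasma cell score, from 5 members, differed by 0.03. The labels set this mouse apart in nothing, so no biological explanation from the design was tested.

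Markers of the muscle wall, stroma and acid-secreting glands were lower in tumours, by -2.67 for smooth muscle, -1.64 for fibroblasts and -3.89 for parietal cells. One common dilution of the muscle wall cannot be told apart from other causes: among members with a mean of at least 8 in unaffected antrum, 15 smooth muscle members shifted by -3.04 and 4 nerve, glia and Cajal cell members by -1.95, a gap of -1.10 (exact permutation p 0.00155) that rests on Ano1, which rose by 1.00, and without Ano1 is -0.11 (exact permutation p 0.690). Uneven and even amounts of acid-secreting tissue among the samples outside tumours cannot be told apart: the parietal score of the 10 members below the top of the scale had an SD of 0.254 over those 16 arrays, neither under the 0.25 nor over the 0.5 set for the test, against a shift of -2.80. A difference in dissection between tumours and antrum, such as less of the wall below the mucosa or less acid-secreting tissue, and a change of cell types in the tumour itself both stay open, because the labels do not record how the tissue was dissected.

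The further values of gp130WT replicate 6 were list scores of 8.78 for cytokines and chemokines (other gp130WT arrays 7.77 to 8.00), 8.99 for macrophages and dendritic cells (7.59 to 7.94), 8.49 for T and NK cells (7.57 to 7.82) and 9.47 for mast cells (8.05 to 8.27). Among its genes, Cd74 stood at 14.02 (9.69 to 10.39), H2-Aa at 13.28 (9.45 to 9.93), Lyz2 at 11.54 (9.41 to 10.38), Duoxa2 at 10.30 (7.60 to 8.77), Cpa3 at 9.19 (6.34 to 7.34), Timp1 at 7.98 (6.09 to 6.74) and Reg3g at 7.36 (4.84 to 5.61). In gp130WT replicate 1 the squamous epithelium score was 8.32 (6.19 to 6.61) and the smooth muscle score 11.11 (10.22 to 10.47). Its genes Ltf at 9.13 (5.16 to 6.15), Cldn2 at 7.74 (4.62 to 5.87), Des at 12.89 (11.73 to 12.15), Synm at 12.75 (11.30 to 11.87), Dpt at 11.45 (10.31 to 10.78) and Pnpla3 at 9.48 (6.91 to 7.47) were high, and Fabp3 at 13.19 (13.65 to 13.99) was low. Single values stood apart in gp130WT replicate 2 (Ier3 at 10.86, others 9.87 to 10.30), replicate 3 (Wdr92 at 7.28, others 7.52 to 7.68) and replicate 5 (H2-Bl at 5.70, others 4.80 to 5.17).

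Unaffected replicate 6 scored 9.77 for immediate-early genes (other unaffected arrays 8.66 to 9.11) and 10.92 for parietal cells (11.47 to 11.79). Its genes Socs3 at 11.87 (8.95 to 10.18), Stat3 at 12.32 (11.60 to 11.88), Il6st at 9.72 (9.03 to 9.27), Timp1 at 9.20 (7.17 to 8.04) and Tkt at 13.23 (12.08 to 12.46) were high. Atp4a at 14.66 (15.21 to 15.55), Id2 at 9.77 (10.94 to 11.61), Pik3c2g at 7.12 (7.85 to 8.34) and Sp5 at 6.06 (7.14 to 7.69) were low in it. Unaffected replicate 3 scored 8.14 for macrophages and dendritic cells (7.29 to 7.69) and 7.99 for T and NK cells (7.57 to 7.75), with Pnpla3 at 6.52 (5.39 to 5.63). In unaffected replicate 5, Cd24a stood at 11.44 (others at most 10.45) and Arrdc3 at 9.16 (7.96 to 8.50).

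Among tumours, replicate 3 had a pentose phosphate score of 11.02 (other tumours 11.36 to 11.50), H2-Bl at 6.37 (7.54 to 8.55), Acox2 at 8.13 (8.88 to 9.54) and Pnpla3 at 6.17 (4.99 to 5.49). Tumour replicate 5 had Il11 at 8.33 (5.84 to 6.74) and Ghrl at 10.92 (7.68 to 9.11), and replicate 2 had Elovl6 at 11.01 (9.94 to 10.42) and Rheb at 11.17 (10.72 to 10.92). Erbb2 stood at 10.75 in tumour replicate 1 (10.39 to 10.54), Chia1 at 7.90 in replicate 4 (5.62 to 6.54) and Hamp2 at 5.19 in replicate 7 (5.63 to 5.85).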

How the results depend on the processing

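The offset of 50, the floor at the threshold, the centring of each array, the stricter filter, the omission of gp130WT replicate 6 with unaffected replicate 6 and the random lists were chosen after seeing the data; the other alternatives were planned. Of 87 gene counts under an alternative, 84 stayed within 1.5 times the count reported, and of 75 list counts 70 did. A fold change of at least 2 left 1969, 195 and 2750 genes (tumour versus unaffected, unaffected versus gp130WT, tumour versus gp130WT), because it asks for more than the test does. Camera called 1, 0 and 0 lists, where the permutation test called 32, 13 and 34; the cause was not tested. Of the lists the permutation test called, 26, 10 and 27 lay outside the central 95% of 10000 random lists of like brightness, which take no account of the correlation between genes, and 10 lists not called between the genotypes did too. Leaving out 1 array gave 8 (without gp130WT replicate 8 or unaffected replicate 6) to 16 lists (without unaffected replicate 7) between the genotypes; the cause was not tested. Without background correction the T and NK cell list shifted by -0.50 (adjusted p 0.00341) between tumour and unaffected antrum, against 0.01 as reported (adjusted p 0.824); the cause was not tested. For single lists, 2971 of 3151 results under an alternative kept direction and side of the threshold, 147 no longer passed, 31 passed only there, 1 turned its direction (the T and NK cell list) and 1 without a test moved. For named genes, 11989 of 12432 kept both, 439 no longer passed, 4 passed only there and 0 turned.

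Between tumour and unaffected antrum the gene count ran from 8018 (stricter filter, 11765 genes tested) to 10030 (no filter, 28902 genes), apart from the count of probes (12837) and the fold threshold. Between the genotypes it ran from 1454 without gp130WT replicate 6 and unaffected replicate 6 to 2048 with an offset of 50, with 1473 for no filter and 1501 without background correction, apart from 2630 probes, the fold threshold and single arrays left out (1366 to 2063). No filter called 72.6% of the genes reported for this comparison, the omission of those 2 arrays 69.6% and no background correction 75.5%. In the permutation test of lists that omission ended the oxidative phosphorylation, Wnt, tuft and B and plasma cell calls between the genotypes (adjusted p 0.0538 to 0.0732). It added the interferon (0.00597) and MHC class II (0.0106) lists there. Between tumour and unaffected antrum it ended the tuft call (0.0626). Tumour versus gp130WT antrum ran from 8710 to 11293, apart from 13946 probes and the fold threshold. With the replicate block, the number the labels share across groups, 8957, 1869 and 9742 genes and 30, 9 and 34 lists passed. The number was not taken as pairing. Each gene's group mean was first subtracted, and the remaining values of same-numbered arrays were correlated. For unaffected antrum and tumour the correlations were 0.0365 to 0.324 (over 0.1 in 5 of 8). For gp130WT and unaffected antrum they were -0.324 to 0.294 (1 of 8), and for gp130WT antrum and tumour -0.146 to 0.0800 (0 of 8). Not every array correlated best with its own number (3 of 8 tumour and 4 of 8 unaffected arrays in the first case). In that case the mean correlation was 0.178 for the same number and -0.0256 for other pairs. The subtraction nearly fixes the second mean once the first is given, so it adds no separate evidence. A relation between same-numbered gp130FF samples, such as a shared batch, therefore stays open. Background correction from detection p-values, filters on detection p-values and a block or permutation within slides were not run, since those columns were not assignable to samples. Signal over background limits genes near the threshold, and their folds are understated. Without background correction, with deposited values under 1 set to 1, 37 of 79 called list shifts moved by over 1.5 times. With no filter 20 did, but the lists could hold further members there. Leaving out 1 array moved 0 of the 79 shifts of lists that passed by over 1.5 times, but 30 of the 44 of lists that did not. This is a ratio to the reported shift, and for a shift near 0 a small change exceeds 1.5 times. The contrast is therefore partly set by which lists passed.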

Other observations

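In tumours against gp130WT antrum, the acute phase and antimicrobial list shifted by 2.73 at the smallest possible p (adjusted p 2.55e-04; adjusted p = 0.234 with an estimated correlation), with 12 of 19 members higher and 3 lower; with no filter the shift was 1.81. Involucrin (Ivl), above threshold on none of the gp130WT arrays, was at least 66.4-fold higher. The water channel Aqp5 rose by 3.32 ± 0.32 (SE, n = 8 arrays per group, here and below), the growth factor Areg by 2.89 ± 0.27 and the gastrokine Gkn3 by 1.72 ± 0.19, and the alarmin Il33 was 6.05-fold higher (SE of the log2 difference 0.29). The squamous list shifted by 1.37 (adjusted p 0.00179; adjusted p = 0.531 with an estimated correlation), with 4 of 9 members higher and a median member at 0.39 (1.83 times the shift without background correction, and a shift of 0.63 with no filter), and the proliferation list by 0.73 (adjusted p 0.00149; adjusted p = 0.531 with an estimated correlation), with 21 of 32 higher and 2 lower (22 and 2 adjusted over the list alone). Ribosome biogenesis genes shifted by 0.24 (adjusted p 0.0244; adjusted p = 0.764 with an estimated correlation), 17 of 27 higher and 6 lower; between the genotypes (0.14, adjusted p 0.0919) they passed without unaffected replicate 7 (0.0266). The lists of IL-6 family genes (-0.17, adjusted p 0.0143; adjusted p = 0.483 with an estimated correlation; 3 of 9 higher, 4 lower; -0.10 with no filter) and mTOR components (-0.09, adjusted p 0.00137; adjusted p = 0.524 with an estimated correlation; 9 of 28 higher, 11 lower) fell slightly, the former not without background correction (adjusted p 0.119). The adipocyte list shifted by -1.07 (adjusted p 2.55e-04; adjusted p = 0.803 with an estimated correlation) although its median member stood at 0.34: 4 of 7 members rose, while the lipase Lpl fell by 6.33 ± 0.13. B and plasma cell markers shifted by -0.31 (adjusted p 0.00179; adjusted p = 0.753 with an estimated correlation), with 1 of 5 higher and 2 lower and a median member at 0.04 (shift -1.23 without background correction and -0.20 with no filter). Surface mucous markers, at 0.28, did not pass (adjusted p 0.0770; 4 of 10 higher, 1 lower), but passed without tumour replicate 1 (0.0289) or 3 (0.0185), with a floor at the threshold (0.0358) and with the stricter filter (0.0444).

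Between unaffected and gp130WT antrum, further lists did not pass in the exact permutation test. Among metabolic lists these were glycolysis (-0.05, adjusted p 0.425; 1 of 16 higher, 3 lower), sterol and fatty acid synthesis (0.08, 0.507; 5 of 24 higher, 1 lower), the pentose phosphate pathway (0.19, 0.0546; 1 of 7 higher; passing without gp130WT replicate 4 or 5 or unaffected replicate 3 or 5, 0.0324 to 0.0497) and the ATF4 response (-0.05, 0.728; 1 of 20 higher, 3 lower). Proliferation markers (-0.02, adjusted p 0.928; 1 of 32 higher) and neutrophil markers (0.01, adjusted p 0.928; 0 of 5 passed) did not pass either. Fibroblast markers, at -0.26, did not pass (adjusted p 0.0589, with 2 of 20 lower), but passed without gp130WT replicate 2 (0.0450) or 5 (0.0368) or unaffected replicate 7 (0.0266). Part of this shift is Col1a2 (-2.71), a gene with a wide gap between the groups.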
